A study of Homo sapiens with 6 samples.

How the data were processed

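The series holds 6 libraries, 3 labelled as treated with 50 nM of a small interfering RNA against EIF4G2 and 3 with 50 nM of a control small interfering RNA, in cells labelled Hep3B. Per the labels' protocols, total RNA was extracted with Trizol, poly(A) RNA was isolated with oligo-dT beads, and paired-end libraries were sequenced on an Illumina HiSeq instrument. The protocol text also speaks of an adipose type, while the other labels give liver and a hepatocellular carcinoma line. Groups and replicate numbers were taken from the sample titles. The submitters' processing notes name HISAT2 2.0 and StringTie 1.3.0 without saying what each did. The genome build, the annotation and the use of strand in counting are not given in the sources used here.

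The authors deposited a single table of 60612 genes with, per library, a count and an FPKM value, and with gene coordinates, Gene Ontology terms and KEGG pathways. The deposited counts are whole numbers but behave as rounded estimated counts. Of 57 low FPKM values rescaled to reads, only 19.3% lay within 0.1 of a whole read. Per the file headers, the other measure is FPKM, and the authors list 0.0001 FPKM where the count is 0. The estimated counts were therefore used as already rounded to whole numbers. Gene intervals overlapped GENCODE release 29 on GRCh38 for 99.9% of 58394 shared identifiers, and 72.7% had the same start and end, so coordinates are given as GRCh38. No column of sample values was left unused.

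The design written before the data were examined named limma on log2(FPKM + 1) for a table without counts and edgeR's quasi-likelihood test on counts if the table held raw counts. The table held counts, although estimated ones, so edgeR on the rounded estimates is the main test and limma on log2(FPKM + 1) is given as an alternative. The 2-fold threshold was therefore applied to edgeR's fold change, while the design had placed it on the log2(FPKM + 1) scale. Rows with the same symbol were reduced to the row with the highest mean FPKM, and genes with at least 0.5 FPKM in at least 3 libraries were kept, which left 13748 genes. TMM factors lay between 0.985 and 1.02. The model held the group only, p-values are two-sided, and they were adjusted by the Benjamini-Hochberg method over all tested genes. Standard errors are the absolute log2 fold change divided by the square root of the quasi-likelihood F. Software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, mgcv 1.9.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

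Total counts lay between 63351653 and 72863628 per library, and mitochondrially encoded genes took 8.03% to 9.02% of them. A count of 0 is given with an upper limit of 3 counts. These limits cover counting error only, since no molecular identifiers were used. The edgeR common coefficient of biological variation was 19.4%. Pearson correlations of log2 CPM across genes were 0.975 to 0.979 within groups and 0.96 to 0.965 between groups, where genes are not independent replicates. The first principal component held 41.6% of the variance and separated the groups. No pair of libraries agreed within sampling noise, since the chi-square per gene within groups was at least 68.5.

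Before the data were examined, 41 gene lists were fixed, among them 4 lists of markers of other cell types. Lists with at least 5 tested members, 39 in all, were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry. With an estimated correlation 2 lists held, S phase and DNA replication among them. Some lists missed the threshold although their estimated correlation lay under the preset 0.01, so a miss does not by itself show correlated genes. Fry asks whether the genes of a list move, on balance, one way, and does not compare the list with other genes. Annotation terms with 10 to 300 tested genes were tested against the 11112 tested genes with at least 1 term. Named genes were EIF4G2, the 12 largest rises and 12 largest falls on the log2(FPKM + 1) scale, and up to 4 members with the smallest p of each list. The rises and falls had to pass edgeR's adjusted p of 0.05, have a mean of at least 2 FPKM in the higher group, have groups that did not overlap, and carry no clone, locus or pseudogene name. LIPA, CTR9, CDKN1A, EIF4G1, EIF4G3 and the hepatocyte and epithelial genes listed at fixed levels were looked up after the data were seen. Some genes that the rule takes, and the other list that held with an estimated correlation, are not reported here.

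The edgeR step was tested on simulated counts for the same 13748 genes. It recovered 90%, 48%, 18.4% and 2% of genes changed 4-fold, 2-fold, 1.5-fold and 1.3-fold, and of its 88 calls 5 were of unchanged genes and 4 were of the 26 genes of a list shifted as a whole. That list was recovered by camera and 0 of 38 other lists were called. Alternatives tried were other pseudocounts, filters, scalings, a replicate block, limma settings, summing rows that share a symbol and leaving out each library. Added after the data were seen were DESeq2, library totals, robust edgeR, limma on log2(FPKM + 1) beside edgeR, and the removal of overlapping genes or of genes whose replicates differ at least 3-fold.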

Results

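Messenger RNA was measured by paired-end sequencing of poly(A)-selected RNA in 6 libraries from cells labelled Hep3B, a human hepatocellular carcinoma line. A set of 3 libraries came from cells given 50 nM of a small interfering RNA against EIF4G2 (siEIF4G2), and the other 3 from cells given 50 nM of a control small interfering RNA (siNC). EIF4G2, also called DAP5 or p97, is a translation initiation factor related to EIF4G1 that lacks the part that binds EIF4E. The deposited counts summed to 72863628, 66420028 and 63351653 in siEIF4G2 replicates 1, 2 and 3, and to 69551246, 67372193 and 70933933 in siNC replicates 1, 2 and 3. Levels are given as CPM, a gene's counts relative to the library total scaled with edgeR's TMM factors, as mean ± SD with n = 3 libraries per group. The labels do not say that the replicates were separate cultures, so p-values measure only the spread between these libraries, which may be technical.

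EIF4G2 was lower in each of the 3 siEIF4G2 libraries than in each of the 3 siNC libraries. The gene (ENSG00000110321) lies on chromosome 11 from 10797050 to 10808929, minus strand, in GRCh38 coordinates. Its level was 178, 180 and 199.8 CPM in siEIF4G2 replicates 1, 2 and 3, against 1103, 913 and 998 CPM in siNC replicates 1, 2 and 3. The means were 186 ± 12.2 CPM and 1005 ± 95 CPM, so EIF4G2 was 5.41-fold lower after silencing, with a log2 fold change of -2.44 (SE 0.09; edgeR adjusted p = 0.000207). An exact two-sided permutation test of this gene alone gave p = 0.1, the smallest value that 3 libraries against 3 allow. The EIF4G2 interval overlaps that of CTR9, and CTR9 read 84.3 ± 3.80 CPM in siEIF4G2 and 81.0 ± 3.64 CPM in siNC (edgeR adjusted p = 0.476). Its relatives EIF4G1 and EIF4G3 had log2 fold changes of 0.15 and -0.34 (edgeR adjusted p = 0.0442 and 0.0114).

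**Figure D1:**
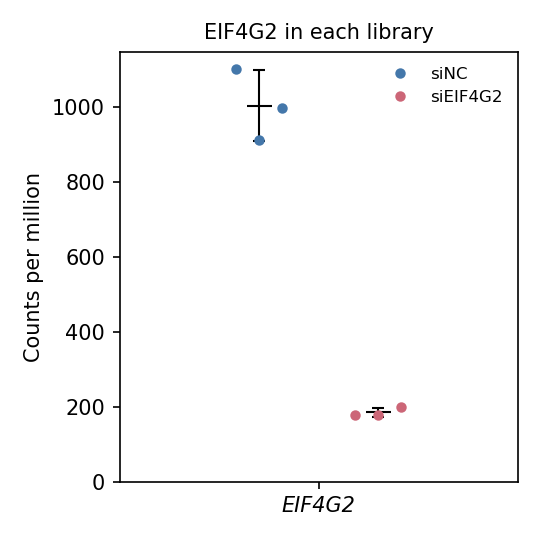
EIF4G2 level in CPM (vertical axis, from 0) in each library. Points are libraries, horizontal ticks the group mean and bars the SD (n = 3). The siEIF4G2 libraries sit between 178 and 199.8 CPM and the siNC libraries between 913 and 1103 CPM.

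The comparison of siEIF4G2 with siNC asked which transcripts change when EIF4G2 is silenced. Of the 12 largest falls taken by the rule for named genes, 8 were protein-coding genes, among them GDF15, a stress-induced secreted cytokine, which went from 216 ± 10.8 to 20.4 ± 2.66 CPM, 10.6-fold lower. DKK3, a secreted member of the Dickkopf family, was 6.80-fold lower, ACTA2, smooth muscle actin, 5.53-fold lower, and PSG4, a pregnancy-specific glycoprotein, 4.2-fold lower, where reads may be shared with its close paralogs. NT5E, the cell-surface 5'-nucleotidase CD73, was 4.13-fold lower, PLAAT2, a phospholipase and acyltransferase, 3.74-fold lower, CCL5, a chemokine, 3.49-fold lower, and ATXN10 3.32-fold lower. Among the rises, CD3EAP, a subunit of RNA polymerase I, was 4.24-fold higher, GANAB, the catalytic subunit of glucosidase II, 2.30-fold higher (584 ± 21.2 against 254 ± 8.97 CPM), MYBL2, a transcription factor of proliferating cells, 2.25-fold higher, MAGT1, a magnesium transporter and oligosaccharyltransferase subunit, 2.04-fold higher, and NOLC1, a nucleolar chaperone, 2.0-fold higher. Adjusted p from edgeR was between 0.000207 and 0.00149 for all 13 of these genes, and each had its 3 siEIF4G2 values on one side of its 3 siNC values.

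Of 13748 genes tested, 4597 passed an edgeR adjusted p of 0.05, 2182 higher and 2415 lower after silencing. Of these, 488 changed at least 2-fold, 132 higher and 356 lower. The 3 values of one group lay wholly above those of the other for 50.6% of tested genes, where chance gives 10%. The count of genes changed at least 2-fold depends on the scale, since limma on log2(FPKM + 1) gave 104 such genes, 20 higher and 84 lower. Over the called genes the median absolute log2 fold change was 0.47. On simulated counts for the same 13748 genes, few of them changed, the test recovered 90% of genes changed 4-fold, 48% of those changed 2-fold and 18.4% of those changed 1.5-fold. The real calls reached smaller changes, so these shares do not give the share of real changes that was missed.

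**Figure D2:**
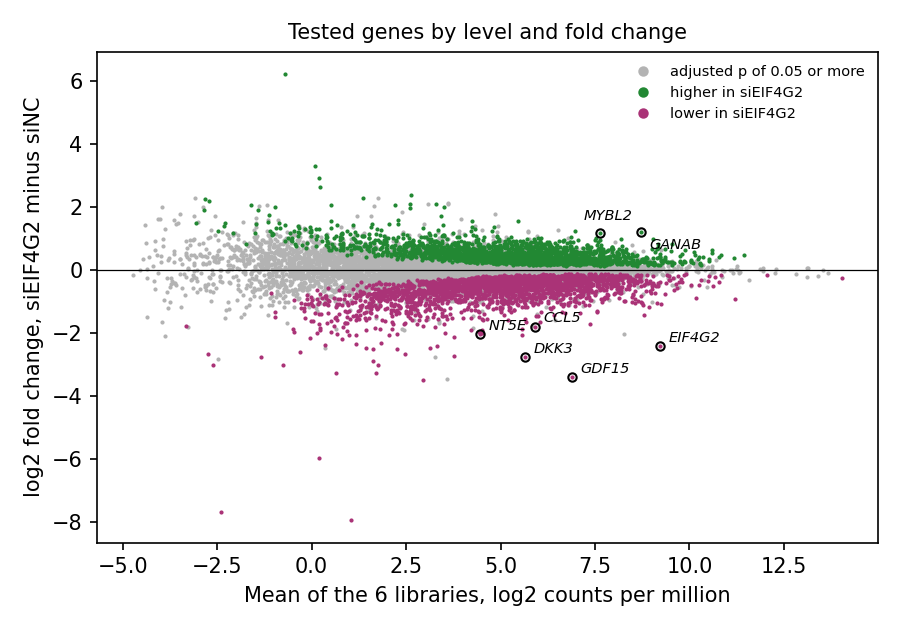
The 13748 tested genes by mean level over the 6 libraries (horizontal axis, log2 CPM) and log2 fold change of siEIF4G2 minus siNC (vertical axis). Coloured points are the 2182 higher and 2415 lower genes past edgeR's adjusted p of 0.05; EIF4G2 and 6 further named genes are circled.

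The rule for named genes also took several for which the counts are uncertain. CD3EAP overlaps ERCC1, DKK3 overlaps USP47, and ACTA2 overlaps FAS and STAMBPL1, and the counting is not stated to use strand. SNHG4, a noncoding RNA whose interval overlaps MATR3, read 65.6 ± 5.03 CPM in siEIF4G2 against 22.4 ± 2.47 CPM in siNC. Small RNA genes inside larger genes were also named, although poly(A) libraries do not capture small RNAs as such. SNORD30 and SNORD22 both lie inside SNHG1, yet SNORD30 was higher (1.54 ± 0.14 against 0.62 ± 0.15 CPM) and SNORD22 lower (0.034 ± 0.024 against 2.27 ± 0.45 CPM). MIR4707 read 1.22 ± 0.097 CPM in siEIF4G2 against 0.0146 CPM in siNC, inside HAUS4. MIR1244-2 and SNORD14C were higher, and MIR3648-1, MIR6772 and MIR3189 lower, the last inside GDF15. The edgeR calls of SNORD14C, MIR6772, TRAF3 and APEX1 were near the threshold and were each lost on leaving out any of several libraries. In those leave-outs, which have fewer libraries, log2 fold changes were 1.27 to 1.54, -2.62 to -2.30 and 1.10 to 1.37 for the first 3. That of APEX1 was 1.23. With all 6 libraries they were 1.52, -2.66, 1.37 and 1.23. TRAF3, an adaptor of innate immune signalling, read 40.9 ± 0.40 CPM in siEIF4G2 against 15.9 ± 9.09 CPM in siNC (adjusted p = 0.0367), and without siNC replicate 2 its adjusted p was 0.105. APEX1, a DNA repair endonuclease, read 176 ± 61.2 against 74.6 ± 1.84 CPM (adjusted p = 0.0155), and 0.0519 without siNC replicate 2 and 0.0509 without siNC replicate 3. SNORD14C had adjusted p between 0.0515 and 0.0692 without siEIF4G2 replicate 1 or 3 or siNC replicate 1 or 3. MIR6772 had adjusted p between 0.0708 and 0.0877 without siEIF4G2 replicate 1 or 2 or siNC replicate 2 or 3. TRAF3 also missed the threshold without siNC replicate 3 (adjusted p = 0.0671) and without each of siEIF4G2 replicates 1, 2 and 3 (0.0801 to 0.0835). With no filter on low values the adjusted p was 0.0536 for SNORD14C, 0.0559 for TRAF3 and 0.0919 for MIR6772.

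Most genes of the interferon response fell. Of 37 tested members of the list of interferon response and double-stranded RNA sensing genes, 34 fell, 0 rose and 3 did not pass, with 35 falls adjusted over the list alone. The median log2 fold change was -0.93. IFIT1, which binds viral RNA lacking 2'-O methylation, went from 495 ± 19.7 to 261 ± 3.27 CPM, and IFIT3, its partner, from 407 ± 9.44 to 205 ± 6.64 CPM. OAS3, an oligoadenylate synthetase, went from 478 ± 21.7 to 234 ± 6.63 CPM, and ISG15, a ubiquitin-like protein, from 507 ± 14.8 to 243 ± 12.1 CPM. Camera with its preset correlation gave an adjusted p of 2.59e-23 for the list, and adjusted p = 0.0718 with an estimated correlation. IFIT1 and IFIT3 share an annotated interval with LIPA, which was itself lower (log2 fold change -0.80). The antigen presentation list moved the same way, with 12 of 16 tested members lower and 1 higher, also adjusted over the list alone (camera adjusted p = 5.33e-05, and adjusted p = 0.0745 with an estimated correlation). HLA-E was 1.86-fold lower, and PSMB9, PSMB10 and PSMB8, the immunoproteasome subunits, 2.44-fold, 1.63-fold and 1.61-fold lower, where PSMB8 and PSMB9 overlap and HLA genes share reads with one another. Of 14 tested acute phase and NF-kB targets, 10 fell and 0 rose, also adjusted over the list alone, among them NFKB2 (1.79-fold lower), RELB (2.56-fold lower), IL32 (2.92-fold lower) and CSF1 (1.67-fold lower). Camera gave that list an adjusted p of 2.8e-06, and adjusted p = 0.0928 with an estimated correlation.

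The lists of mitosis and of S phase and DNA replication passed upward with the preset correlation, and only the latter also with an estimated one (adjusted p = 0.0966 and 0.0323 with an estimated correlation). Of 48 tested mitosis genes, 40 rose, 0 fell and 8 did not pass, with 42 rises adjusted over the list alone, and the median log2 fold change was 0.57. KIF2C and KIF4A, mitotic kinesins, were 1.58-fold and 1.83-fold higher, KIF11 was 1.66-fold higher, and CKS2, a subunit of cyclin-dependent kinase complexes, 1.61-fold higher. Camera gave the mitosis list an adjusted p of 8.41e-20 with the preset correlation. Of 49 tested genes of S phase and DNA replication, 31 rose and 0 fell, and adjusted over the list alone 33 rose and 1 fell. RRM2, a ribonucleotide reductase subunit, went from 80.2 ± 2.56 to 147 ± 5.43 CPM, and UHRF1, which maintains DNA methylation, from 77.5 ± 2.64 to 140.2 ± 4.16 CPM. E2F2 and RFC3 were 1.95-fold and 1.65-fold higher. Camera gave this list an adjusted p of 1.77e-09 with the preset correlation. Of 18 tested cyclins, cyclin-dependent kinases and inhibitors of G1, 6 rose and 3 fell, also adjusted over the list alone, and the list did not pass (camera adjusted p = 0.24). Its median log2 fold change was 0.11 and its mean -0.003, opposite in sign. CDC25A and CDKN2C rose 1.72-fold and 1.42-fold, SKP2 rose 1.40-fold and RBL1 1.49-fold. CDKN1A, a member of this list that was looked up after the data were seen, differed at least 4-fold between replicates in both groups (121 ± 69.3 against 492 ± 284 CPM; edgeR adjusted p = 0.0726).

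Of 32 tested apoptosis regulators, 8 fell and 2 rose, or 11 and 2 adjusted over the list alone. TNFRSF10B, a death receptor, was 1.54-fold lower, BAK1 1.39-fold lower and MCL1 1.3-fold lower, while CYCS, cytochrome c, was 1.46-fold higher. Camera gave that list an adjusted p of 0.0265, which was 0.0597 without siNC replicate 1 and 0.13 among genes that overlap no other counted gene, and adjusted p = 0.138 with an estimated correlation.

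The lists of cytosolic ribosomal proteins and of ribosome biogenesis passed upward with the preset correlation, by small amounts. Of 79 tested cytosolic ribosomal protein genes, 39 rose, 0 fell and 40 did not pass, with 44 rises adjusted over the list alone, and the median log2 fold change was 0.20. RPSA, RPL12, RPS12 and RPLP0 were 1.48-fold, 1.34-fold, 1.42-fold and 1.35-fold higher. Many ribosomal protein genes have near-identical pseudogenes, so their counts are uncertain. Camera gave an adjusted p of 9.99e-09, and adjusted p = 0.358 with an estimated correlation. Of 40 ribosome biogenesis genes, 26 rose and 3 fell, or 28 and 4 adjusted over the list alone, with a median of 0.30 (camera adjusted p = 3.28e-08, and adjusted p = 0.106 with an estimated correlation). NCL, nucleolin, went from 439 ± 5.37 to 642 ± 12.9 CPM, NOP56 was 1.54-fold higher, NOP16 1.43-fold higher, and NOLC1 is given above. Of 48 tested translation initiation factors, 14 rose and 5 fell, also adjusted over the list alone, and the list did not pass (camera adjusted p = 0.11, and 0.0188 with no filter on low values). EIF4EBP2, which restrains EIF4E, was 2.05-fold lower and EIF4H 1.79-fold lower, and EIF1AX and EIF5A were each 1.63-fold higher. Of 11 messenger RNAs reported to be translated through EIF4G2, 3 rose (CDK1, CDKN1B, HMGN3) and 2 fell (HSPA1B, HSPA1A), while adjusted over the list alone 4 rose and 2 fell. HSPA1A and HSPA1B are near-identical copies and share reads. The call of HSPA1B was lost without siEIF4G2 replicate 1 (adjusted p = 0.0549), siNC replicate 1 (0.0564) or siNC replicate 2 (0.0544). Camera gave that list an adjusted p of 0.706, with a median log2 fold change of -0.22 and a mean of -0.008 while the test pointed up. Messenger RNA levels do not show whether the translation of these messenger RNAs changed.

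**Figure D3:**
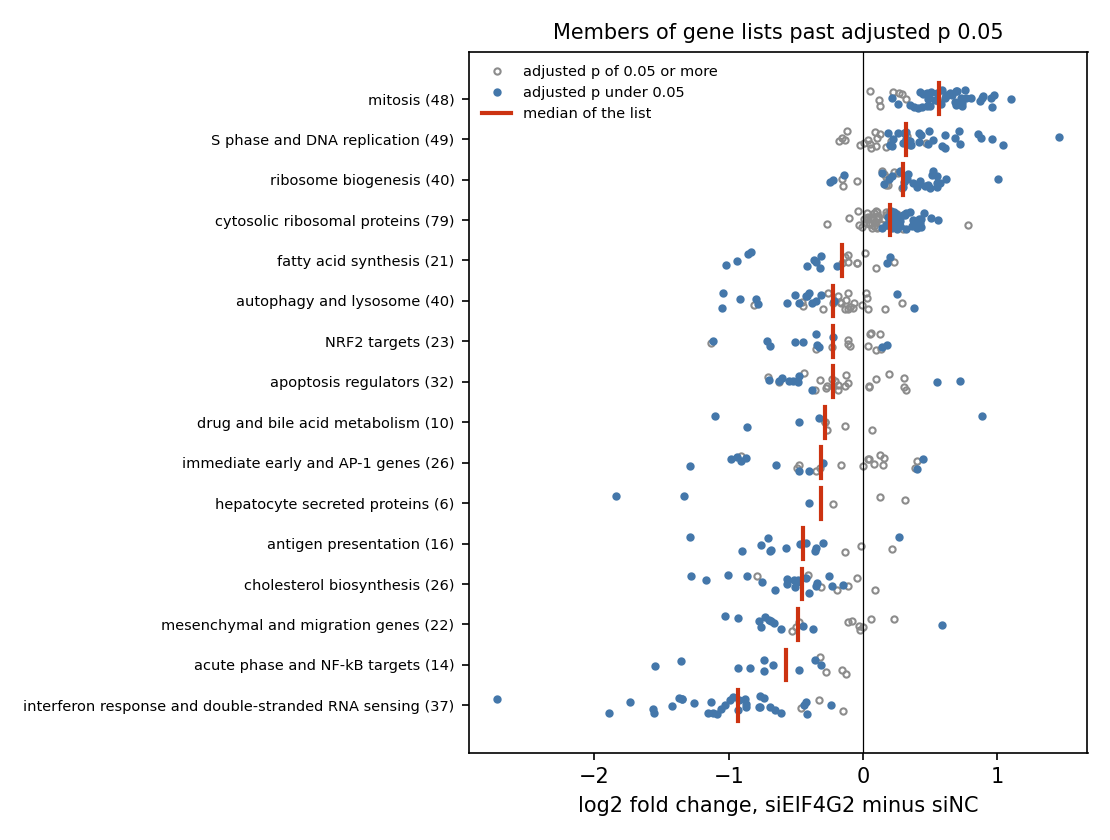
Log2 fold change of siEIF4G2 minus siNC (horizontal axis) for each tested member of 16 of the 17 lists past camera's adjusted p of 0.05 with the preset correlation, with the number tested in parentheses. Filled points passed edgeR's adjusted p of 0.05 and red bars mark medians, which run from -0.93 for the interferon list to 0.57 for mitosis.

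The lists of cholesterol biosynthesis and fatty acid synthesis passed downward with the preset correlation. Of 26 tested cholesterol biosynthesis genes, 19 fell, 0 rose and 7 did not pass, also adjusted over the list alone, with a median log2 fold change of -0.46. MSMO1, a sterol demethylase, went from 65.8 ± 1.74 to 29.2 ± 1.5 CPM, and NSDHL, LSS and HSD17B7, further enzymes of the pathway, were 1.68-fold, 1.82-fold and 2.0-fold lower. Camera gave an adjusted p of 4.97e-09, and adjusted p = 0.0885 with an estimated correlation. Of 21 tested fatty acid synthesis genes, 10 fell and 2 rose, with 3 rises adjusted over the list alone (camera adjusted p = 0.00349, and adjusted p = 0.106 with an estimated correlation). SCD, the stearoyl-CoA desaturase, went from 3105 ± 62.7 to 1619 ± 47.4 CPM, and ACSS2, LPIN1 and ACSL1 were 2.03-fold, 1.81-fold and 1.78-fold lower.

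The lists of autophagy and lysosome genes, mesenchymal and migration genes, NRF2 targets and immediate early genes also passed downward with the preset correlation, and none of the 4 passed with an estimated one (adjusted p = 0.0745 to 0.358 with an estimated correlation). Of 40 tested autophagy and lysosome genes, 15 fell and 2 rose, or 20 and 2 adjusted over the list alone (camera adjusted p = 2.89e-05, and adjusted p = 0.126 with an estimated correlation). MCOLN1, a lysosomal ion channel, ATG5, NPC1, a cholesterol transporter, and PSAP, a precursor of lysosomal activator proteins, were 1.89-fold, 2.06-fold, 2.07-fold and 1.42-fold lower. Of 22 tested mesenchymal and migration genes, 11 fell and 1 rose, or 13 and 1 adjusted over the list alone (camera adjusted p = 6.32e-05, and adjusted p = 0.0745 with an estimated correlation). LAMB3, a laminin chain, FN1, fibronectin, and ITGA3, an integrin, were 1.90-fold, 1.69-fold and 1.36-fold lower. Of 23 tested NRF2 targets, 9 fell and 2 rose, or 10 and 2 adjusted over the list alone (camera adjusted p = 0.0226, 0.0622 with limma on quantile-normalized values, and adjusted p = 0.358 with an estimated correlation). HMOX1, heme oxygenase, AKR1C3 and TKT were 2.17-fold, 1.36-fold and 1.27-fold lower. Of 26 tested immediate early and AP-1 genes, 9 fell and 2 rose, or 10 and 3 adjusted over the list alone (camera adjusted p = 0.0245, 0.0521 without siEIF4G2 replicate 3, and adjusted p = 0.358 with an estimated correlation). DUSP4, DUSP1 and DUSP5, phosphatases of MAP kinases, were 2.45-fold, 1.92-fold and 1.88-fold lower, and JUNB was 1.57-fold lower.

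Most hepatocyte genes were at or near 0 in both groups. Of 45 genes for secreted proteins of hepatocytes, 39 had a mean under 1 CPM and 20 were listed at 0 in all 6 libraries. ALB, AFP, APOA1, APOB, TTR, FGB and GPC3 were each listed at 0 counts in every library. A count of 0 allows up to 3 counts, or 0.0412 to 0.0474 CPM at these depths, for counting error only. Only 6 secreted protein genes were tested, and 3 of them fell, also adjusted over the list alone, led by CFB, complement factor B (2.51-fold lower), VTN, vitronectin (3.58-fold lower), and C3 (1.32-fold lower). Camera gave that list an adjusted p of 0.0431. It was 0.0561 without siEIF4G2 replicate 1, 0.0862 without siEIF4G2 replicate 2 and 0.0597 without siNC replicate 1, and adjusted p = 0.272 with an estimated correlation. It also missed the threshold with no filter on low values (0.0726) and with limma on every FPKM or TPM scale tried (0.0709 to 0.0823). For drug and bile acid metabolism, 10 of 37 genes were tested, of which 4 fell and 1 rose, also adjusted over the list alone. ABCC3, POR and SULT1A1 were 2.14-fold, 1.82-fold and 1.39-fold lower and CYP1B1 was 1.85-fold higher. Camera gave an adjusted p of 0.0362, which was 0.0506 without siEIF4G2 replicate 2, 0.0597 without siNC replicate 1 and 0.0672 without siNC replicate 3, 0.0583 with no filter on low values and 0.0518 with limma on quantile-normalized values, and adjusted p = 0.358 with an estimated correlation. Of 12 tested hepatocyte transcription factors, 3 rose and 2 fell (camera adjusted p = 0.381), and of 10 tested fetal liver and hepatocellular carcinoma markers, 2 rose and 2 fell (camera adjusted p = 0.799).

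Markers of endothelial cells and of leukocytes were mostly below the filter. It was passed by 8 of 12 cholangiocyte markers and by 10 of 18 fibroblast and stellate cell markers. Of 14 endothelial markers, 3 were tested and CDH5 fell, and of 18 leukocyte markers, 2 were tested and both CSF1R and CD68 fell; camera was not run on lists this short. Of 8 tested cholangiocyte markers, 2 fell and 0 rose, with KRT7, a keratin, going from 834 ± 72.6 to 392 ± 34.7 CPM (camera adjusted p = 0.15, and 0.0331 without siNC replicate 3). Of 10 tested fibroblast and stellate cell markers, 6 fell and 3 rose (camera adjusted p = 0.24). PDGFRB was 2.29-fold lower and COL1A1 1.35-fold lower, while COL3A1 was 1.28-fold higher.

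The other 15 lists that were tested did not pass camera. Among 38 ATF4 and integrated stress response targets, 8 rose and 13 fell (camera adjusted p = 0.434). GDF15, SQSTM1 and WARS1 of that list were lower and PSAT1 was 1.62-fold higher. Among 29 genes of the endoplasmic reticulum unfolded protein response, 4 rose and 10 fell (camera adjusted p = 0.139), and among 20 heat shock genes 7 rose and 5 fell (camera adjusted p = 0.343), with HSPD1 1.76-fold and HSP90AA1 1.56-fold higher. Counts of rises and falls were 2 and 6 of 23 for fatty acid oxidation, 1 and 5 of 22 for glycolysis, and 3 and 5 of 21 for targets of hypoxia-inducible factor. They were 4 and 10 of 73 for nuclear genes of oxidative phosphorylation, 1 and 1 of 13 for mitochondrially encoded genes, and 2 and 5 of 18 for epithelial junctions. They were 3 and 6 of 18 each for targets of TGF-beta and of YAP, 1 and 2 of 10 for Wnt targets, and 5 and 4 of 26 for the small RNA pathway. They were 4 and 2 of 24 for nonsense-mediated decay factors and targets, and 3 and 3 of 15 for replication-dependent histones, whose median log2 fold change was -0.02 and mean 0.12. Adjusted over the list alone, rises and falls were 4 and 11 for the unfolded protein response, 7 and 6 for heat shock, 3 and 7 for fatty acid oxidation and 4 and 5 for hypoxia targets. They were 4 and 6 for oxidative phosphorylation, 1 and 0 for mitochondrially encoded genes, 2 and 6 for epithelial junctions and 4 and 6 for YAP targets, and did not move for the others. Camera adjusted p lay between 0.189 and 0.986 for these 12 lists.

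**Figure D4:**
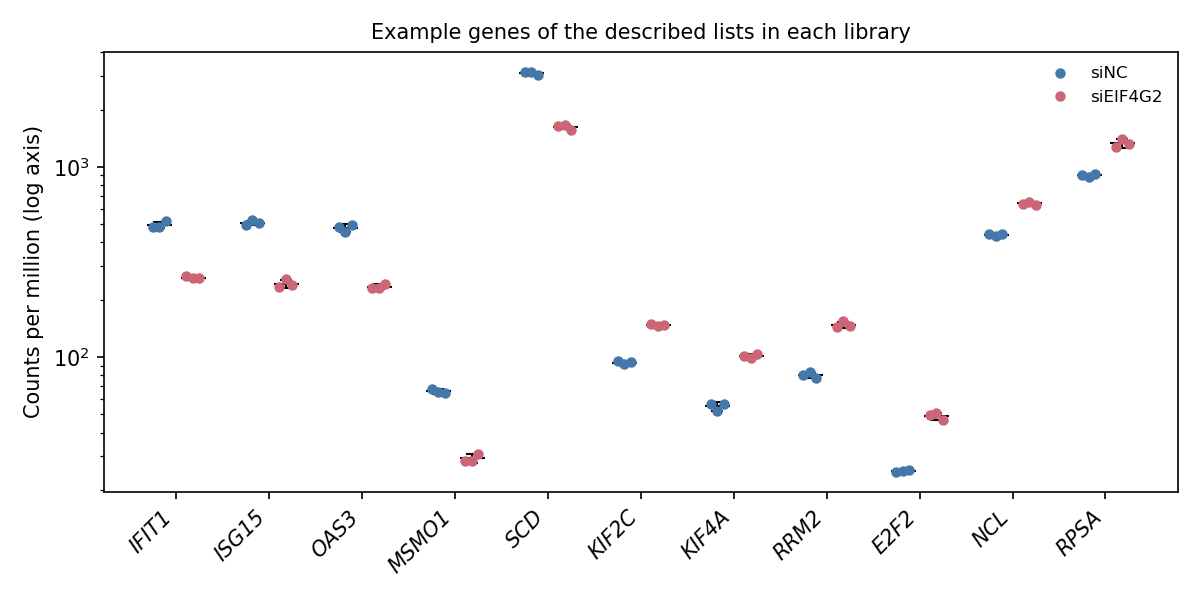
Levels of 11 genes from the described lists in each library, in CPM on a log axis. Points are libraries, ticks the group mean and bars the SD (n = 3). IFIT1 to SCD were lower and KIF2C to RPSA higher in all 3 siEIF4G2 libraries than in all 3 siNC libraries.

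The annotation terms in the deposited table gave a wider view. Of 3261 terms tested with a one-sided Fisher's exact test, 278 passed after Benjamini-Hochberg adjustment, 124 among the higher and 154 among the lower genes. The test uses the gene calls above and treats genes as independent, although genes of a term can move together. Its p-values therefore do not measure the spread between libraries. Among the higher genes, 66 of 141 genes of the centromeric region were called where 23.6 were expected by chance (Fisher's exact adjusted p = 3.92e-13), and 87 of 237 genes of mRNA splicing through the spliceosome where 39.6 were expected (Fisher's exact adjusted p = 9.28e-11). DNA replication had 63 of 153 (25.6 expected) and rRNA processing 60 of 163 (27.3 expected). Among the lower genes, 112 of 287 cell surface genes were called where 57.2 were expected (Fisher's exact adjusted p = 7.53e-11), and 31 of 44 genes of type I interferon signalling where 8.77 were expected (Fisher's exact adjusted p = 5.89e-10). Collagen-containing extracellular matrix had 69 of 155 (30.9 expected), lysosomal membrane 100 of 270 (53.8 expected) and cholesterol biosynthesis 21 of 32 (6.38 expected). Restricting the calls to genes changed at least 2-fold left 10 terms, all among the lower genes.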

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

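DESeq2, robust edgeR, library totals, limma on log2(FPKM + 1) beside edgeR, and the removal of overlapping genes or of genes with a 3-fold replicate spread were chosen only after the data were seen. The count of genes past adjusted p 0.05, 4597 in the report, was 3352 to 5343 under the refits, and each refit shared at least 3204 of the calls, all in the same direction. The log2 fold change of the EIF4G2 level lay between -2.50 and -2.35; it had no value among non-overlapping genes, and DESeq2 gave no lists. No result past its threshold turned its direction, while the median of the uncalled list of EIF4G2-translated messenger RNAs went from -0.22 to 0.05 among non-overlapping genes (list median log2 fold change, mRNAs reported as translated through EIF4G2). The count of genes past adjusted p 0.05 and at least 2-fold, 488 in the report, was 197 with limma on log2(FPKM + 0.5), 104 on log2(FPKM + 1), 104 without a trend, 103 robust, 110 with library weights, 107 after quantile normalization and 288 on log2(TPM + 1), where the pseudocount shrinks the fold changes of low genes by construction. With fewer genes tested, it was 205 at a mean FPKM of at least 2 and 311 among non-overlapping genes. The 17 lists became 2 with an estimated correlation and 30 with fry, and the 278 terms became 10 with calls of at least 2-fold. The cause was not tested. Estimated correlations were 0.00124 for S phase, -0.0397 for mesenchymal and -0.0368 for antigen presentation genes, under the preset 0.01, while others lay above it. Camera p of these 3 lists still rose, from 1.82e-10 to 0.00166, 1.78e-05 to 0.00917 and 1.37e-05 to 0.00955. For them the values argue against a higher correlation as the cause. Missing the threshold with an estimated correlation therefore does not by itself show that the genes of a list are correlated. Leaving out each library in turn gave 3352 to 4134 genes, 435 to 499 genes changed at least 2-fold, 14 to 17 lists, 213 to 284 terms and -2.50 to -2.36 for EIF4G2. Of the genes taken by the rule, 11 lost their call without siNC replicate 3, the most in any refit, and no refit ended the camera call of more than 3 lists, which were hepatocyte secreted proteins, drug and bile acid metabolism, NRF2 targets, apoptosis regulators or immediate early genes. In simulation with few changed genes, 48% of 2-fold and 18.4% of 1.5-fold changes were recovered; the real calls, with a median absolute log2 fold change of 0.47, reached smaller changes.

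With the replicate number as a block, 3736 genes passed, and the count of genes past adjusted p 0.05 and at least 2-fold was 435. Calls were lost for hepatocyte secreted proteins, SNORD14C, MIR6772, ONECUT2 and ZNRF3, and for no other named gene or list. Deviations of same-numbered libraries correlated at 0.004, 0.034 and 0.052 across genes, and siEIF4G2 replicate 1 correlated best with siNC replicate 3 (0.028), so the data do not show that the numbers pair the samples.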

Other observations

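The test of failed estimates was chosen only after the result was seen. Several genes looked up after the data were seen were abundant in both groups. CPS1, a urea cycle enzyme of hepatocytes, was at 2554 ± 223 CPM in siEIF4G2 and 2372 ± 107 CPM in siNC, and H19, an imprinted noncoding RNA of fetal liver, at 1154 ± 306 and 1678 ± 79.7 CPM. KRT8, a keratin of simple epithelia, was at 1434 ± 109 and 1580 ± 27.1 CPM, and VIM, the filament protein vimentin, at 718 ± 18.5 and 730.3 ± 25.7 CPM. The epithelial genes CDH1 and EPCAM were under 1 CPM, CDH1 at 0.40 ± 0.026 and 0.33 ± 0.16 CPM and EPCAM at 0 and 0.019 CPM. CDKN2A, which encodes inhibitors of the cell cycle, was at 76.7 ± 1.68 and 70.9 ± 4.03 CPM. Interferon-stimulated genes such as IFIT1 were abundant in both groups, while IFNB1 and IFNL1, which encode interferons, had at most 14 and 22 counts in any library.

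In libraries labelled Hep3B, hepatocyte genes were near 0, with 39 of 45 secreted protein genes under 1 CPM. The tables argue against failed estimates of very abundant genes as the whole cause, since hepatocyte regulators, which are less abundant, had a median of 0.0232 CPM over 14 genes chosen after the result was seen. Of these 12 were under 1 CPM and FOXA1 was the highest at 15.3 CPM, while 12 of 26 factors on the list of hepatocyte transcription factors passed the expression filter. A mislabelled cell line stays open. No biological explanation was tested.

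Among 11226 genes of at least 5 CPM, 351 differed at least 3-fold between replicates of a group. Of these 5 (1.4%) were called, against 37.7% of the others, and a spread this wide by itself makes a call unlikely. CDKN1A read 41.5, 169 and 152 CPM in siEIF4G2 and 672, 164 and 641 CPM in siNC replicates 1, 2 and 3, and the 2 rows of MATR3 ranged 15.1-fold and 28.9-fold over the libraries while their sum ranged 1.5-fold. Of the 351 genes, 42.5% overlapped another gene, against 32% of genes of the same abundance. The ratio was 1.33 (95% bootstrap interval 1.17 to 1.49), above 1, so reads shared between overlapping genes may add to the spread. It lay just under the 1.5 set beforehand, and most of the 351 overlapped no other counted gene. Shared reads were therefore argued against as the whole cause, not as a part of it. Counts estimated over many annotated isoforms were argued against too, with a ratio of median transcript numbers of 1 (95% bootstrap interval 0.857 to 1). The source of the spread stays open, and no biological explanation was tested.

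The interferon list was lower and the mitosis list higher in siEIF4G2, with medians of -0.93 and 0.57. GC content and transcript length were argued against as the whole cause, since after removal of their trend across genes the medians were -0.95 and 0.55. The choice among the scalings tried was argued against for the interferon list, whose median nearest 0 over 4 other scalings was -0.79. Those 4 scalings differed little, with a median log2 fold change over all tested genes of 0.0079 to 0.0341. A scaling far from these was not tested. A higher interferon response to the control siRNA cannot be told apart from an effect of EIF4G2 silencing, because there were 0 untreated libraries. Both stay open, and an effect of the siRNA on other transcripts was not tested.

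Results were compared over the 10 splits of the 6 libraries into groups of 3, too few for a share under 0.05. The real split gave 4597 genes and the highest of the others 4, and for genes changed at least 2-fold the values were 488 and 3. For terms they were 278 and 0, and for lists 17 and 14. In each case 1 of the 10 splits, the real one, gave a result as large. Every other split mixes both treatments within each group, so a real difference widens the within-group spread and lowers the calls. Terms are tested on called genes, so with few calls almost none could pass. The low counts of genes and terms in the other splits therefore do not show what chance alone gives. Camera with its preset correlation called 6 to 14 lists in the other splits. The treatments are mixed unevenly in those splits, so part of their difference remains between the groups. These list counts do not show what chance alone gives either.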
